A study of Mus musculus with 7 samples.

How the data were processed

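Gene expression was measured by RNA sequencing of inguinal white adipose tissue, the subcutaneous fat pad of the groin, from NOD/ShiLtJ mice, a strain that develops autoimmune diabetes. The series holds 7 libraries. In 3 of them, called sham here, the mice had received KRBH buffer. In the other 4, called imBAT here after their titles, the mice had received a protein fraction above 100 kDa taken from buffer conditioned by brown adipocytes. Groups were taken from the treatment label of each library and replicates were numbered in accession order, so a replicate number only names a library. The labels do not say whether each library came from a separate mouse, so the p-values measure the spread between these libraries.

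The authors deposited 1 table of raw read counts per gene for the whole series. Per the labels' protocols, RNA was isolated with a kit for lipid-rich tissue, libraries were sequenced on a NovaSeq 6000, and reads were aligned with STAR 2.7.9a to the primary assembly of Ensembl release 101. Per the submitters' processing notes, featureCounts 2.0.3, Subread, Salmon 1.5.2, edgeR and limma were also used, with no role given. The strand setting and the treatment of reads that match several places are not given in the sources used here. Antisense pairs such as Xist and Tsix, overlapping genes such as Nnat inside its host gene, and near-identical copies such as the Sprr2 genes and the alpha-globin genes may therefore share reads, and their values are uncertain to that extent.

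The table held 55774 rows, of which 287 repeated a gene identifier with identical counts and were dropped, leaving 55487 genes. All 7 count columns were matched to a library by name. Counts totalled 41025786 to 44983250 per sham library and 43360208 to 63650016 per imBAT library, and 55227 of the gene identifiers were present in GENCODE M21 on the GRCm38 build, from which the coordinates in the text were taken. No pair of libraries of the same group was alike within sampling noise: a chi-square test of their counts gave 22.5 to 241.2 per degree of freedom.

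The comparison was made with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test (robust fit), TMM scaling, the default expression filter (minimum count 10) and a model of group alone, which leaves 5 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 26393 genes tested and called under 0.05. A standard error of a log2 fold change was taken as its size divided by the square root of F. Values per library are TMM-scaled CPM, that is counts relative to the scaled library total, and means are given with their SD. For a gene with no count in any sham library, the fold is a lower limit set by a floor of 3 counts over the group.

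Lists of genes for pathways and for the cell types that groin fat can hold were written before the data were examined, as were the rule for naming genes, the tests and all alternatives except a pair named below. The lists with 5 or more tested members, 42 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Members were also tested singly, with adjustment over all genes and over the list alone. The sex-linked list had 2 tested members and got no list test. The named genes are the 12 with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap and whose mean was at least 1 CPM (clone names and antigen receptor segments excluded), up to 4 members per list with the smallest p, and 16 genes of adipocyte, insulin and macrophage biology fixed by name. Members that went against their list, the immunoglobulin and imprinted genes, Fads3, Ptprc, Cd3e, Cidec, Dgat2, Thrsp, Me1, Orm1, Otop1, Rbp4, Cd4, Ctla4 and Ms4a1 were chosen after their values were seen. Some genes of the lists and of the rule are not reported here; they were kept in the fits, list tests and list counts.

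The alternatives were RLE and upper-quartile scaling, no expression filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom with quality weights, the number that opens each title as a block, leaving out each library in turn, and an adjusted p under 0.10. A fit on counts thinned to the smallest library total and a fit with a lymphoid score (the mean log2 CPM of the T cell and B cell lists) as covariate were chosen after seeing the data. The steps were tested on simulated counts over 26024 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. Of these edgeR recovered 42% and 76%, with 12 false calls among 130. DESeq2 recovered 65% and 82%, with 56 false calls among 203, and voom 39% and 73%, with 10 false calls among 122. In the data a far larger share of genes was called (43.5%), so these rates need not hold for the real comparison. Each list test recovered both changed lists of 10 with no false call. The simulated genes varied independently, whereas members of the real lists move together (estimated correlation 0.96 for MHC class II). The simulation therefore does not check the list tests for correlated genes.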

Results

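The comparison asked how inguinal white adipose tissue of NOD mice differed after injection of large proteins secreted by brown adipocytes. Mice with a blood glucose of 190 to 230 mg/dL were injected under the skin for 7 days. The imBAT mice received the protein fraction at 1.5 mg/kg body weight and the sham mice received buffer. Tissue was taken 2 to 8 weeks later, with the week of each animal not stated. The data were 3 sham and 4 imBAT libraries, with 41025786 to 44983250 counts per sham library and 43360208 to 63650016 per imBAT library. Xist, the transcript of the inactive X chromosome, stood at 1180 to 1502 TMM-scaled CPM in every library, and genes of the Y chromosome had 0 to 14 counts per library in all.

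The imBAT libraries carried far more adipocyte RNA and far less lymphocyte RNA than the sham libraries. Leptin (Lep), the hormone released by fat cells, rose from 1.09 ± 1.07 CPM (SD, n = 3) to 240.2 ± 71.7 CPM (n = 4), and adiponectin (Adipoq) rose 8.57-fold. Genes of fatty acid and triglyceride synthesis, extracellular matrix and mitochondrial respiration rose with them. Genes of T cells, B cells, MHC class II and the cell cycle fell, among them Ptprc, the pan-leukocyte antigen CD45, from 1392 ± 72.4 to 458.8 ± 144.2 CPM. These lists were called with a preset correlation between genes, and none was with an estimated correlation (smallest adjusted p = 0.40). Of 26393 genes tested, 11491 (43.5%) changed, 6407 higher and 5084 lower in imBAT, and 6102 of them by at least 1 on the log2 scale (3768 higher, 2334 lower). The groups did not overlap for 13719 tested genes (52.0%, where chance gives 5.71%), and the first principal component, with 65.7% of the variance, separated them. Upper-quartile scaling moved the median log2 fold change of all genes from -0.01 to -0.25 and the calls to 4722 higher and 8180 lower, 36.6% higher in place of 55.8%. No median of a called list changed sign under that scaling.

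**Figure D1:**
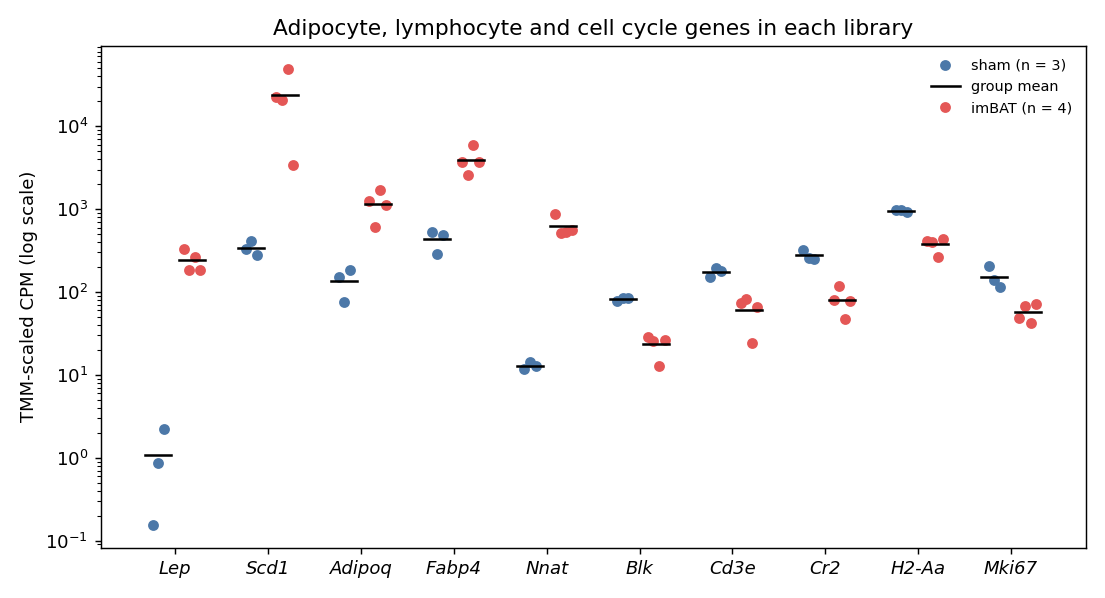
TMM-scaled CPM on a log axis for 10 genes in each of the 7 libraries, with a point per library and a bar at the group mean. Lep, Scd1, Adipoq, Fabp4 and Nnat were higher in every imBAT library than in any sham library, and Blk, Cd3e, Cr2, H2-Aa and Mki67 were lower.

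Among the genes that rose most, 3 had no count in any sham library: Prr32, which was at least 175.3-fold higher, and the cornified-envelope genes Sprr2a3 and Sprr2f, at least 149.2-fold and 126.6-fold higher. Their imBAT levels were low, at 3.59 ± 2.40, 3.05 ± 3.52 and 2.59 ± 3.18 CPM (n = 4), and the Sprr2 pair was highest in imBAT replicate 1 (edgeR log2 fold change, with no floor, 10.24 and 10.00, and 9.08 and 8.64 without that library); with no expression filter the pair was not called (adjusted p = 0.107 for both). Lep rose by 7.76 ± 0.74 on the log2 scale (SE, adjusted p = 0.000816), and by 8.85 without sham replicate 3. Scd1, the stearoyl-CoA desaturase, rose by 6.15 ± 0.88 from 339.8 ± 65.8 to 24160 ± 19060 CPM, with 20780 to 49580 CPM in imBAT replicates 1 to 3 and 3391 CPM in imBAT replicate 4. Sncg (75.4-fold), Pnpla3 (73.8-fold), the growth factor Areg (74.2-fold), albumin Alb (86.1-fold), the fructose transporter Slc2a5 (96.2-fold), Sprr1a (233.4-fold) and the urothelial gene Upk3a (66.6-fold) completed the group. Without sham replicate 1 the log2 fold change was 8.62 in place of 6.21 for Areg and 10.59 in place of 6.06 for Upk3a, since all 8 sham counts of Upk3a lay in that library. Slc2a5 stood at 42.55 CPM in imBAT replicate 3 against 0.65 to 4.83 CPM in the other imBAT libraries, and its log2 fold change was 6.59, and 4.38 without that library; its call was lost without sham replicate 3 (adjusted p = 0.0506). Lep lies on chromosome 6 at 29060220 to 29073877, and Scd1 on chromosome 19 at 44394455 to 44407879 (GRCm38).

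Among the 12 genes with the largest fall, Hamp2, a relative of the iron hormone hepcidin, fell 40.6-fold from 3.05 ± 2.10 to 0.08 ± 0.09 CPM (log2 fold change -5.34, and -6.47 without imBAT replicate 4). Apoc3 fell 7.49-fold, Abca13 6.29-fold, the prostaglandin D synthase Ptgds 6.22-fold, the odorant receptor genes Olfr109 and Olfr165 5.63-fold and 5.44-fold, and Mir142b, at a microRNA locus of blood cells, 5.55-fold. Aire, the autoimmune regulator expressed in thymus and in rare cells of lymph nodes, fell 4.90-fold from 12.1 ± 0.4 to 2.46 ± 0.68 CPM (adjusted p = 0.000835). Adam6b (5.16-fold), Vsx1 (5.01-fold), Tdgf1 (4.97-fold) and Loxhd1 (4.89-fold) completed the group. Adam6b, Vsx1 and Tdgf1 had values above 0 in the fit with the lymphoid score as covariate, but were not called there.

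White adipocyte genes rose nearly as a set: 26 of 27 tested members rose, over all genes and adjusted over the list alone, with a median log2 fold change of 3.11, and Agt at 0.95 ± 0.55 was not called except without imBAT replicate 2 (log2 fold change 1.29, adjusted p = 0.00709). Fabp4, the fatty acid carrier of adipocytes, rose 9.19-fold to 3974 ± 1370 CPM, the adipocyte master regulator Pparg 6.90-fold, the insulin-responsive glucose transporter Slc2a4 by 3.40 on the log2 scale, the beta-3 adrenergic receptor Adrb3 10.7-fold and the lipid droplet genes Plin1, Plin4 and Cidec 8.75-fold, 10.4-fold and 5.74-fold. The imprinted gene Nnat rose 47.9-fold (log2 fold change 5.58 ± 0.25) and the natriuretic clearance receptor Npr3 59.6-fold. All 30 tested members of the fatty acid and triglyceride synthesis list rose, with the same count adjusted over the list alone and a median of 2.66. The list also holds Orm1, which encodes a secreted plasma protein. Among the members were Gpam (4.72-fold), Srebf1 (3.30-fold), Acsl1 (6.27-fold) and the fatty acid synthase Fasn. Fasn went from 539.6 ± 120.5 to 16040 ± 18410 CPM, with 43090 CPM in imBAT replicate 3 and 2566 to 11620 CPM in the others. Its log2 fold change was 4.89, and 3.65 without imBAT replicate 3. Of 19 lipolysis genes 17 rose under both adjustments, with a median of 2.36, including Prkar2b (11.3-fold) and Pde3b (2.63-fold). The camera test gave adjusted p = 1.25e-13, 2.84e-10 and 4.53e-08 for these 3 lists, and adjusted p = 0.40 with an estimated correlation for each. In the same libraries the medians of the T cell and B cell lists lay at -1.51 and -1.67.

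**Figure D2:**
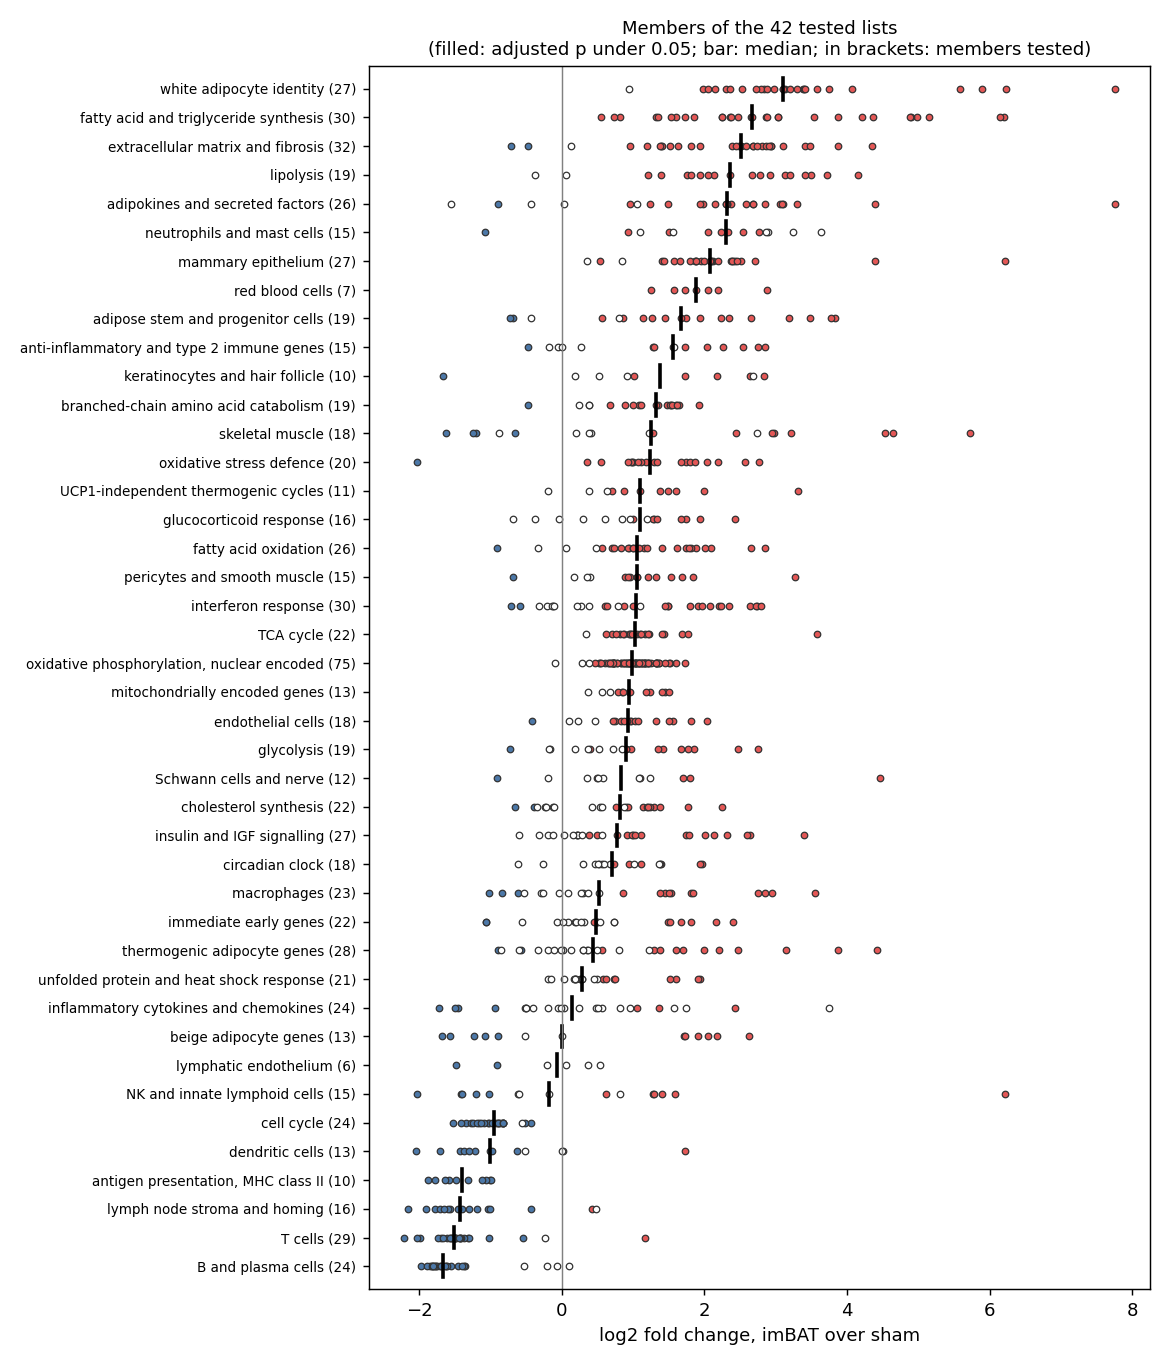
Log2 fold change (imBAT over sham) of each tested member of the 42 tested lists, ordered by median, with filled points for members with adjusted p under 0.05 and a black bar at the median. White adipocyte genes stand at the top with a median of 3.11, and B and plasma cell genes at the bottom with -1.67.

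Mitochondrial genes rose, with list medians of 0.94 to 1.32 on the log2 scale. Of 75 nuclear genes of oxidative phosphorylation, 72 rose (74 adjusted over the list alone) with a median of 0.98, including Cox4i1 (2.24-fold) and Ndufa6 (1.66-fold). Of 13 genes encoded in the mitochondrion 10 rose under both adjustments (median 0.94), including mt-Nd4 (2.83-fold) and mt-Cytb (2.65-fold). Of 22 TCA cycle genes 21 rose (22 over the list alone, median 1.02), with the pyruvate carboxylase Pcx higher by 3.58 on the log2 scale. Of 26 genes of fatty acid oxidation 22 rose and 1 fell under both adjustments (median 1.06), with Cpt2, of mitochondrial fatty acid import, 4.28-fold higher. Of 19 genes of branched-chain amino acid breakdown 16 rose and 1, Ppm1k, fell under both adjustments (median 1.32), with Pccb 3.79-fold and the mitochondrial carrier Slc25a44 2.79-fold higher. Camera gave adjusted p = 1.25e-13, 0.000432, 8.58e-07, 1.32e-06 and 2.55e-05 in that order, and adjusted p = 0.40 with an estimated correlation for each. The white adipocyte list moved with them, with its median of 3.11. Ppm1k was not called without sham replicate 1 or 3 (adjusted p up to 0.0666).

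Genes of glucose use and of insulin action rose in part. Of 19 glycolysis genes 11 rose and 1, Eno3, fell under both adjustments (median 0.90), with hexokinase 2 (Hk2) 6.75-fold and Ldhb 5.52-fold higher. For glycolysis the camera test gave adjusted p = 0.00195, and adjusted p = 0.40 with an estimated correlation. Of 27 genes of insulin and IGF signalling 16 rose and none fell (16 and 1 adjusted over the list alone, median 0.77), among them the insulin receptor Insr (1.70-fold, 163 ± 18.7 to 277.4 ± 33.9 CPM) and Pik3r1 (2.17-fold). Of 26 adipokines and secreted factors 21 rose and 1, Bmp8b, fell (21 and 2 over the list alone, median 2.31). Nrg4, a secreted neuregulin, rose 6.42-fold, the myokine-like Metrnl 5.19-fold and the retinol carrier Rbp4 21.1-fold. Of 22 cholesterol synthesis genes 11 rose and 2, Stard4 among them, fell (13 and 3 over the list alone, median 0.82), with the squalene synthase Fdft1 2.20-fold higher. In camera, adjusted p was 7.82e-05, 7.38e-07 and 0.0313 for insulin signalling, adipokines and cholesterol synthesis, and adjusted p = 0.40, 0.40 and 0.49 with an estimated correlation. The cholesterol list was not called without sham replicate 1 or imBAT replicate 1 (adjusted p up to 0.0583), nor Bmp8b without sham replicate 2 or 3 (up to 0.0698). Adipocyte markers rose beside all of these lists (median 3.11).

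Clock and glucocorticoid-response genes rose in part. Of 18 clock genes 8 rose under both adjustments and none fell (median 0.70, camera adjusted p = 0.00864, and adjusted p = 0.40 with an estimated correlation), including Cry2 (1.92-fold) and Nr1d1 (3.84-fold). Of 16 glucocorticoid-response genes 8 rose under both adjustments and none fell (median 1.10, camera adjusted p = 0.00522, and adjusted p = 0.41 with an estimated correlation), including the glutamine synthetase Glul (3.34-fold) and Klf9 (2.43-fold). Of 20 genes of oxidative stress defence 19 rose and 1 fell under both adjustments (median 1.24, camera adjusted p = 3.46e-06, and adjusted p = 0.40 with an estimated correlation). Gclm, of glutathione synthesis, rose 2.45-fold, while the cystine transporter Slc7a11 fell 4.10-fold from 48.6 ± 2.3 to 11.8 ± 3.7 CPM. Of 21 unfolded protein and heat shock genes 8 rose under both adjustments (median 0.28, camera adjusted p = 0.00783, and adjusted p = 0.48 with an estimated correlation), including Hspb1 (3.03-fold) and Xbp1 (1.65-fold). Immediate early genes were not called as a list (adjusted p = 0.0521, and adjusted p = 0.60 with an estimated correlation) except without imBAT replicate 1 or 3 (adjusted p = 0.0468 and 0.0111). Of its 22 members 10 rose and 2, Nr4a3 and Egr3, fell under both adjustments, with Klf4 3.52-fold and Jun 2.82-fold higher. Nr4a3 was not called without sham replicate 2 (adjusted p = 0.0766) and Egr3 not without sham replicate 3 (0.0556). White adipocyte markers (median 3.11) and the T and B cell lists (-1.51 and -1.67) moved beside these lists.

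Thermogenic genes, those of heat-producing brown and beige adipocytes, rose less evenly. Ucp1, the uncoupling protein on chromosome 8 at 83290352 to 83298452 (GRCm38), was too low to test, with 8, 12 and 8 counts in the sham libraries and 2, 8, 83 and 6 counts in imBAT replicates 1 to 4. Of 28 tested thermogenic genes 12 rose and 2, Bmp8b and Acot11, fell (13 and 2 adjusted over the list alone, median 0.43). The deiodinase Dio2 rose 14.7-fold to 2.61 ± 1.30 CPM, Ppara 4.0-fold, Ebf2 4.62-fold, S100b 3.23-fold and Prdm16 2.45-fold, while Ppargc1a, at 5.87 ± 5.46 in sham and 7.57 ± 3.46 CPM in imBAT, was not called (adjusted p = 0.64) except without sham replicate 1 (log2 fold change 1.47, adjusted p = 0.0377). Cidea rose by 2.47 ± 0.80 on the log2 scale, but its call was lost without sham replicate 2 or 3 or imBAT replicate 3 (adjusted p up to 0.113, log2 fold change 1.44 without imBAT replicate 3). Of 13 beige genes 6 rose and 5 fell (6 and 6 over the list alone), and the median of 0.00 took either sign with the scaling, with Hoxc9 3.28-fold and Slc36a2 4.53-fold higher and Sp100, Ear2, Tnfrsf9, Epsti1 and Tmem26 lower. Tnfrsf9 also encodes a costimulatory receptor of T cells. Sp100 and Epsti1 are interferon-responsive, though of 30 interferon-response genes 18 rose and 2 fell (median 1.05). Of 11 genes of UCP1-independent heat production 8 rose (9 over the list alone, median 1.10), including the creatine kinase Ckb (3.97-fold) and the creatine transporter Slc6a8 (2.14-fold). Camera gave adjusted p = 0.0249 for the thermogenic, 0.88 for the beige and 0.00171 for the UCP1-independent list, and adjusted p = 0.48, 0.92 and 0.40 with an estimated correlation. The thermogenic list was not called without sham replicate 3 (adjusted p = 0.0519). Bmp8b was not called without sham replicate 2 or 3 (adjusted p up to 0.0698), Acot11 without any single sham replicate or imBAT replicate 4 (up to 0.10), and Ear2 without sham replicate 1 or 3 or imBAT replicate 1 or 3 (up to 0.156). General adipocyte markers rose beside these lists (median 3.11).

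Matrix, stromal and vascular genes rose together. Of 32 matrix genes 29 rose and 2, Tnc and Tgfb1, fell under both adjustments (median 2.51), with the collagens Col1a2 and Col6a2 6.43-fold and 5.69-fold, Postn 5.72-fold and Thbs1 2.61-fold higher. Of 19 adipose progenitor markers 15 rose and 2, Cd55 and Icam1, fell (16 and 2 over the list alone, median 1.67), including Mfap5 (11.2-fold), F3 (4.70-fold) and Pdgfra (2.21-fold). Of 18 endothelial markers 14 rose and 1, Pecam1, fell under both adjustments (median 0.93), with Vwf 2.82-fold and Gpihbp1 3.51-fold higher. Of 15 pericyte and smooth muscle markers 11 rose and 1, Des, fell (12 and 1 over the list alone, median 1.06), with Cspg4 9.62-fold and Pdgfrb 2.08-fold higher. Camera gave adjusted p = 1.99e-11, 7.92e-05, 5.24e-05 and 0.000484 in that order, and adjusted p = 0.40 with an estimated correlation for each. Lymphatic endothelium was not called (adjusted p = 0.42, and adjusted p = 0.62 with an estimated correlation); 2 of its 6 tested markers, Mmrn1 and Prox1, fell 2.80-fold and 1.88-fold under both adjustments. Tnc was not called without sham replicate 2 (adjusted p = 0.058), Tgfb1 without any single sham replicate or imBAT replicate 4 (up to 0.0745), Pecam1 without sham replicate 2 or 3 (up to 0.0674), and Cd55 without sham replicate 3 or imBAT replicate 2, 3 or 4 (up to 0.136). White adipocyte markers (median 3.11) and the T and B cell lists (-1.51 and -1.67) moved beside these as well.

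Markers of other tissues of the fat pad also rose. Of 27 mammary epithelium genes 25 rose under both adjustments (median 2.07), including Krt17 (4.37-fold) and the estrogen and progesterone receptors Esr1 (3.68-fold) and Pgr (5.73-fold). All 7 red blood cell genes rose (median 1.88), with Hba-a1 4.54-fold and Alas2 2.38-fold higher. For these 2 lists camera gave adjusted p = 4.67e-08 and 0.00119, and adjusted p = 0.40 with an estimated correlation for both. Of 10 keratinocyte genes 5 rose and 1 fell (6 and 1 over the list alone, median 1.37), with Krt79 6.22-fold higher and Dsg1a 3.18-fold lower. Of 12 Schwann cell and nerve genes 5 rose and 1 fell under both adjustments (median 0.83), among them Sox10 (3.47-fold) and Gap43 (22.1-fold, from 0.04 ± 0.03 CPM), with Cnp of myelin 1.88-fold lower. Camera gave adjusted p = 0.0459 and 0.0264 for keratinocytes and nerve, and adjusted p = 0.40 and 0.49 with an estimated correlation. The keratinocyte list was not called without imBAT replicate 1 (adjusted p = 0.0579), nor the nerve list without sham replicate 3 or imBAT replicate 1, 3 or 4 (up to 0.10). Skeletal muscle was not called as a list (adjusted p = 0.22, and adjusted p = 0.68 with an estimated correlation). Of its 18 tested genes 8 rose (9 over the list alone), with Myl1 23.1-fold higher, and 4 fell under both adjustments, Ttn 2.31-fold, Neb, Mylpf and Mybpc1. Mybpc1 was called only with all libraries or without imBAT replicate 4 (adjusted p up to 0.107 otherwise). Neither tested sex-linked gene was called. Adipocyte and lymphocyte lists moved beside these too, with the medians given above.

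Lymphocyte genes fell. Of 29 T cell genes 27 fell and 1, Gzmb, rose under both adjustments (median -1.51), with Icos 3.97-fold, Foxp3 2.70-fold, Cd3g 2.85-fold and Cd8b1 3.25-fold lower and Cd3e falling from 173.9 ± 21.9 to 61.4 ± 25.6 CPM. Of 24 B and plasma cell genes 20 fell under both adjustments (median -1.67), with Blk 3.53-fold, Bank1 3.45-fold and the complement receptor Cr2 3.42-fold lower. Of 16 lymph node genes 14 fell and 1, Lifr, rose under both adjustments (median -1.44), including the stromal gene Grem1 (4.48-fold lower), Glycam1 of lymph node venules (3.76-fold lower, from 883.1 ± 181.6 CPM) and Cxcr5 (2.96-fold lower). All 10 genes of MHC class II presentation fell under both adjustments (median -1.40), with H2-Aa 2.49-fold and the transactivator Ciita 3.0-fold lower. Of 13 dendritic cell genes 9 fell and 1, Clec10a, rose under both adjustments (median -1.0), with Flt3 3.27-fold and Irf8 2.59-fold lower. Of 24 cell cycle genes 23 fell (24 over the list alone, median -0.96), with Top2a 2.54-fold and Mki67 2.67-fold lower. These 6 lists had camera adjusted p = 1.74e-07, 1.49e-07, 0.000118, 1.33e-05, 0.00232 and 4.53e-08 in that order, and adjusted p = 0.40 with an estimated correlation for each. Natural killer and innate lymphoid genes were not called as a list (adjusted p = 0.98, and adjusted p = 0.99 with an estimated correlation). Of these 15 genes 6 rose and 5 fell under both adjustments (median -0.18, mean 0.32), with Nkg7 and Klrk1 2.65-fold and 2.66-fold lower beside Il7r, Eomes and Prf1, and camera's direction was upward, as was Areg, a member of the list. Lymphocyte genes were lowest in imBAT replicate 3. Gzmb was not called without sham replicate 2 (adjusted p = 0.0526), Lifr without sham replicate 2 or 3 or imBAT replicate 1 or 4 (up to 0.144), Eomes without sham replicate 3 (0.0578), and Prf1 without any single sham replicate or imBAT replicate 4 (up to 0.0764). The white adipocyte list rose in the same libraries (median 3.11).

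**Figure D3:**
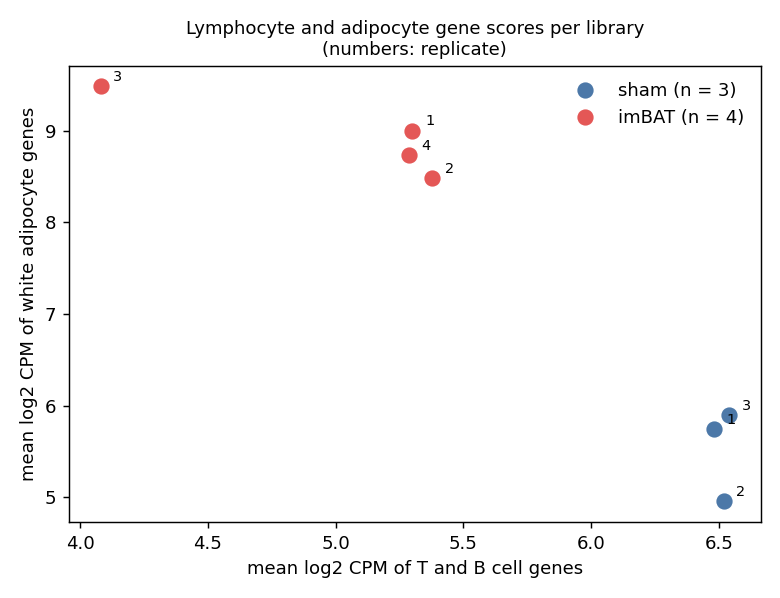
Mean log2 CPM of the white adipocyte list (vertical axis) against that of the T and B cell lists (horizontal axis), with a point per library numbered by replicate. Sham libraries lie between 6.48 and 6.54 on the lymphocyte axis, and imBAT libraries between 4.08 and 5.38.

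Macrophage and inflammatory genes went both ways. Of 23 macrophage markers 11 rose and 3, Itgax, Timd4 and Mpeg1, fell (11 and 4 over the list alone, median 0.52, camera adjusted p = 0.0984, and adjusted p = 0.66 with an estimated correlation). Adgre1, which encodes F4/80, rose 11.7-fold but stood at 20.3 CPM in imBAT replicate 2 against 124.3 to 232.4 CPM in the other imBAT libraries, and Cd68 was not called (36.0 ± 2.3 and 51.7 ± 16.9 CPM, adjusted p = 0.12) except without imBAT replicate 2 (adjusted p = 0.00469). The macrophage list was called without imBAT replicate 2 as well (adjusted p = 0.00103). Of 15 genes of type 2 immunity 9 rose and 1, Tgfb1, fell under both adjustments (median 1.55, camera adjusted p = 0.00864, and adjusted p = 0.40 with an estimated correlation), including the resident macrophage receptors Cd163 (7.20-fold) and Mrc1 (6.71-fold) and the eotaxin Ccl24 (4.81-fold). Of 24 inflammatory genes 3 rose (2 over the list alone) and 4 fell under both adjustments, and the list was not called (median 0.14, mean 0.32, camera downward with adjusted p = 0.996, and adjusted p = 0.998 with an estimated correlation). Tnf fell 2.74-fold from 15.8 ± 1.9 to 5.75 ± 2.04 CPM, with Ccl5 (2.84-fold), Tnfaip3 (1.92-fold) and Il12b also lower, and Lcn2, Cxcl1 and Ptgs2 higher. Of 30 interferon-response genes 18 rose and 2, Gbp5 among them, fell (20 and 3 over the list alone, median 1.05, camera adjusted p = 0.00146, and adjusted p = 0.49 with an estimated correlation), with Ifit3b 6.65-fold and Iigp1 2.00-fold higher. Of 15 neutrophil and mast cell genes 8 rose and 1, Cxcr2, fell (13 and 1 over the list alone, median 2.30, camera adjusted p = 0.000973, and adjusted p = 0.40 with an estimated correlation), with the mast cell proteases Mcpt4 and Cma1 4.93-fold and 5.80-fold higher. Il12b was not called without sham replicate 2 or 3 or imBAT replicate 2 (adjusted p up to 0.0978), Cxcl1 without sham replicate 2 or 3 (up to 0.0551), Ptgs2 in 5 of 7 such fits (up to 0.138), Timd4 without sham replicate 1 or 2 or imBAT replicate 2 (up to 0.0758), Mpeg1 without sham replicate 3 (0.0653), and Tgfb1 without any single sham replicate or imBAT replicate 4 (up to 0.0745). White adipocyte markers rose (median 3.11) and the T and B cell lists fell (-1.51 and -1.67) in the same libraries.

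Of the 42 lists, 35 were called, 29 higher and 6 lower, by camera with the preset correlation. Camera with an estimated correlation called none (smallest adjusted p = 0.40, and 1 list with an unadjusted p under 0.05). Fry called 35 as well, but it asks whether members changed, not whether they changed more than other genes. With 43.5% of all genes called, its count is not separate support. Its test for change in either direction called all 42 lists. The count of changed genes was 7519 without sham replicate 2, with 3024 lower, and 3074 were lower without sham replicate 3. With the lymphoid score as covariate 2 genes were called by edgeR, Nnat and Fads3, both higher, and 3550 had an unadjusted p under 0.05; that score and the group had a correlation of -0.88.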

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

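All tests below were chosen after the results were seen, except the search for single libraries far from their group. In the imBAT group 259 values were searched for a library far from the other 3 (by Dixon's ratio of the gap to the range; the sham group of 3 is too small), and 23 were found where chance alone gives 12.95; genes of a cell type move together, and the set searched grew as genes were added to the text. Of these 16 concerned imBAT replicate 3. It lay below the other imBAT libraries for Ms4a1 (ratio 0.959), Cxcr5 (0.91), Cd4 (0.907), Madcam1 (0.90), Il7r (0.888), Epsti1 (0.88), Cd3g (0.876), Icam1 (0.875), Blk (0.856), Tnfrsf9 (0.83), Ctla4 (0.83) and H2-Aa (0.8293), and for the scores of the lymph node (0.911), B and plasma cell (0.89) and MHC class II (0.872) lists. It lay above them for Adrb3 (0.881). Ms4a1 stood at 20.04 CPM there against 46.2 to 47.9 CPM in the other 3. imBAT replicate 2 lay below the others for Cd163 (0.928), Hba-a1 (0.851) and the type 2 immune list (0.938). imBAT replicate 4 lay above them for Mertk (0.94) and Cxcr2 (0.888), and imBAT replicate 1 for Nnat (0.84) and Mylpf (0.841).

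The first pattern weighed is the fall of lymphocyte genes. For sequencing depth, thinning all libraries to the smallest total left 46 T and B cell genes called lower, against 47 of 53 as deposited. Thinning keeps each gene's share of its library, so it shows only that the calls did not need the extra depth. imBAT replicate 4, with 43360208 counts, lay within the sham range of 41025786 to 44983250. Its lymphoid score was 5.29, against 6.48 to 6.54 in sham. A smaller share of lymph node tissue in the imBAT libraries remains a candidate explanation. The 9 node genes that are not lymphocyte genes had a median log2 fold change of -1.04 and 7 of them fell, Grem1 and Glycam1 furthest. They are part of the lymph node list reported above, so their fall was already known when this was asked. Without 1 library 4 to 7 fell (4 without sham replicate 2 or 3), and the median stayed at or below -1.0. Whether the node was dissected differently or the same node sat in a larger fat pad was not tested, and a change of the lymphocytes by the treatment, or by the 2 to 8 weeks before sampling, stays open as well.

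The second pattern, first tested as a single comparison that did not decide it and then split by cell type, is that white adipocyte genes rose by more than markers of other cells of the pad. If only the node share differed, cell types absent from the node would rise alike. The mean log2 CPM of the white adipocyte list, less that of the mammary epithelium list, was higher in imBAT by 1.19 (exact two-sided permutation p = 0.0571), which does not decide it. The difference was 2.48 against the endothelial list and 1.48 against the red blood cell list (exact p = 0.0286 each, the smallest that 3 against 4 libraries can give), and 1.09 against the mast cell genes Mcpt4, Cma1, Cpa3 and Tpsb2 (exact p = 0.0571). Vessels, blood and mast cells also occur in lymph nodes, so a smaller node share would by itself let them rise less than adipocyte genes, and for these types it cannot be told apart from a further cause. More fat tissue per pad after treatment may contribute and was not tested.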

How the results depend on the processing

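The lymphoid score and the thinned counts were chosen after seeing the data. Under RLE scaling, no filter, the stricter filter, DESeq2 (18 genes without an adjusted p), voom, an adjusted p under 0.10 and thinning, 10378 to 14080 genes changed. RLE, no filter, the stricter filter, DESeq2, voom, the block and thinning shared 10046 to 11482 calls, in the same direction, with the 11491, and upper-quartile scaling 9806; Lifr and Ptgs2 lost their calls under the latter, and the cholesterol, keratinocyte and nerve lists under the stricter filter. Upper-quartile scaling gave 8180 lower genes because it moved the median of all genes to -0.25. Without 1 library, 7519 to 11403 genes changed (lowest without sham replicate 2) and 3024 to 5097 were lower (3024 and 3074 without sham replicates 2 and 3). Of 202 called genes on which the text rests, 181 to 197 kept their call without 1 library, 183 with no filter, and at least 191 in the other planned fits. The calls lost with no filter were those of Sprr2a3, Sprr2f, Slc2a5, Upk3a, Cidea, Nr1d1, Ccl5, Sox10, Ighe, Cd3e, Otop1, Me1, Acot11, Cd55, Neb, Mybpc1, Il7r, Fos and Fosb (adjusted p 0.0508 to 0.149), by voom Ighe, Otop1, Ptgs2 and Neb (0.0508 to 0.0966), and with the block Nr1d1, Ighe, Lifr, Madcam1, Clec4g, Ptgs2, Ppm1k, Timd4, Mybpc1, Ear2 and Fos (0.0502 to 0.106). Uncalled values that crossed 0 in some fits were Ppargc1a, Xist, Gnas, Impact, 5 immunoglobulin genes and the medians of the beige, inflammatory, natural killer, lymphatic and muscle lists.

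With the lymphoid score as covariate 2 genes changed, 2 higher and 0 lower by edgeR (3550 with an unadjusted p under 0.05), and 24 lists were called. The score follows the groups (correlation -0.88), so the fit has little left to estimate the group effect from. Of the 202 called genes 180 lost their call and 20 changed sign: Adam6b (0.086), Vsx1 (1.22), Tdgf1 (0.62), Cidea (-0.66), Ccl5 (0.26), Tnfaip3 (0.033), Cd8b1 (0.12), Cd3e (0.31), Madcam1 (0.65), Ccl19 (0.12), Cd4 (0.17), Ctla4 (0.19), Tgfb1 (0.094), Timd4 (0.031), Egr3 (0.18), Ear2 (0.19), Tnfrsf9 (0.31), Il7r (0.53), Eomes (0.044) and Prf1 (0.46). So did the medians of cholesterol synthesis (-0.067), T cells (0.20) and lymph node genes (0.096). None of the 20 genes was called in that fit either (edgeR adjusted p 0.547 to 0.985). Nor were these lists (camera adjusted p 0.238 to 0.703). Camera with an estimated correlation called 0 of the 35 lists. It uses a larger spread for lists whose genes move together, but that need not be the whole reason. The clock list had an estimated correlation of only 0.049. Its unadjusted camera p was 0.00638 with the preset and 0.081 with the estimated correlation.

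The number that opens each title is shared by 3 sham and imBAT pairs, and its meaning is not stated. Libraries with the same number had correlations of their deviations of 0.10, 0.11 and -0.01, and sham replicates 1 and 2 correlated best with their own number while sham replicate 3 did not, so what the number marks stays open. With the number as a block 10853 genes changed, 6198 higher and 4655 lower, and 37 lists were called. Depth of 41025786 to 63650016 counts limits only genes near the floor, such as Ucp1.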

Other observations

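Genes of the immunoglobulin heavy and kappa chains were chosen after their values were seen. The naive B cell isotype Ighd fell 3.92-fold, from 407.4 ± 45.8 to 104 ± 38.3 CPM, while Ighm, Igkc, Ighg1, Ighg2b, Ighg2c, Ighg3 and Igha were not called. Igkc stood at 711.2 ± 254.2 in sham and 615.3 ± 299.3 CPM in imBAT. Ighe, the IgE heavy chain, fell 14.5-fold, but 137.1 CPM in sham replicate 1 stood against 10.52 and 19.55 CPM in the other sham libraries (log2 fold change -3.86, and -1.97 without sham replicate 1), and it was not called without the expression filter, by voom or with the title number as a block.

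Of 22 imprinted genes, which are expressed from the copy of a single parent and were also listed after seeing the data, 15 rose and none fell (median log2 fold change 1.83). H19 rose 14.6-fold to 11.5 ± 3.2 CPM, Meg3 5.71-fold, Peg10 5.77-fold, Ndn 4.48-fold and Grb10 3.33-fold, while Gnas was not called. Nnat, on chromosome 2 at 157560078 to 157562522 (GRCm38), was the imprinted gene with the largest fold. White adipocyte markers rose beside these genes (median 3.11). In a fit scaled to the white adipocyte list without Lep, 20 of the 22 had values below 0, as nearly all genes did, and Nnat (2.31 ± 0.44, SE) and H19 (0.69 ± 0.53, adjusted p = 0.199) had values above 0.

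The tests below were chosen after the results were seen. For the fit without imBAT replicate 3 only the rule was set beforehand. Its pattern and its scaling to adipocyte genes came from results already seen. The third pattern weighed is that Lep and some lipid synthesis genes rose by more than adipocyte genes. A larger share of the same adipocytes, whether from a smaller node share or not, would leave the ratio of Lep to Adipoq as it was. Its log2 value was higher in imBAT by 5.34 (-2.24 ± 0.48 against -7.58 ± 2.03, SD, exact two-sided permutation p = 0.0286, the smallest possible). Lep was singled out after its rise had been seen, so this p follows from folds already given. Sham Lep was also low, at 0.15 to 2.25 CPM. The ratio goes against that explanation for Lep alone and is not independent support. For lipid synthesis it stays open: 7 of the 30 list members (Dgat2, Fasn, Me1, Orm1, Pnpla3, Scd1 and Thrsp) rose by more than the adipocyte reference over the list alone and 13 by less. Of all 26393 genes 69 lay above the reference and 25239 below it, whether they rose or not (adjusted over all genes). Among the 7, Orm1 encodes a secreted plasma protein and not an enzyme of lipid synthesis. Taken relative to the reference, only Dgat2, Pnpla3 and Thrsp were higher in every imBAT library than in any sham library, and 15 were lower (0.857 each by chance). The rule first asked for the adjusted p alone, which the 7 genes met, and was tightened to non-overlapping libraries after that, because the p-values of such a fit were not checked by simulation. Without imBAT replicate 3 there were 4, so a contribution of that library cannot be told apart with so few libraries. A change of the adipocytes in imBAT, with glucose and insulin per mouse not given, is a hypothesis that stays open.

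Whether thermogenic genes rose beyond adipocyte genes was not decided: 1 of 28 members, Otop1, lay above the adipocyte reference (0 without imBAT replicate 3) and 24 lay below it, as nearly all genes did under that scaling. Whether the 4 lower inflammatory genes fell like lymphoid genes as a whole was not decided: 0 of them remained lower in a fit scaled to the T and B cell lists (edgeR), but that scaling left only 35 of the 5084 lower genes lower, and 1 of the 4, Ccl5, belongs to those lists. That all B lineage cells fell alike was not decided: the log2 ratio of secreted immunoglobulin to naive B cell genes was higher in imBAT by 1.76 (exact two-sided permutation p = 0.0857), with sham replicate 1 above imBAT replicate 2.

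For the gene counts the real split was the most extreme, and 0.0286 is the smallest share that 3 against 4 libraries can give. The other splits mix sham and imBAT libraries, which widens the spread within each side and keeps their counts low. The comparison therefore cannot exclude chance. Of the 35 ways to split the 7 libraries into 3 and 4, 1, the real split, gave 11491 changed genes, and the highest of the others gave 103. For genes higher and lower the real split gave 6407 and 5084, 1 of 35 each, and the highest others 5 and 98. The split that gave 103 genes parts imBAT replicates 1, 3 and 4 from the rest. For the number of lists chance cannot be excluded either: 2 of 35 splits gave 35 or more, the other being that same split, with 37 lists. Splits with 0 changed genes gave 0 to 33 lists. A high count of lists called with the preset correlation is therefore not particular to the real split.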
